A study of Mus musculus with 23 samples.

How the data were processed

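Gene expression was measured in 23 oral tumours of C57BL/6 mice, grown for 21 days, on the Illumina MouseRef-8 v2 array, 1 array per tumour, per the labels. The labels put the tumours in 5 groups. KHR tumours had intact Notch1 (n = 5). KHR-N+/- (n = 4) and KHR-N-/- (n = 5) tumours were of the same type with 1 copy or no copy of Notch1, and KR-N+/- (n = 5) and KR-N-/- (n = 4) tumours were of a second type with the same genotypes. No KR group with intact Notch1 was analysed here. The labels do not expand the codes KHR and KR. They number biological replicates within each group and do not say which tumours came from different animals, so p-values measure the spread between these tumours. RNA was extracted with Trizol and copied into biotin-labelled cRNA with an Ambion MessageAmp kit, per the labels' protocols.

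The deposited scanner table gives for each array and probe a mean bead intensity on a linear scale, not background-subtracted and not normalized between arrays, judged from its values. It also gives the number of beads and a detection p-value, which per the file headers is the detection p of the probe, a rank against the array's negative control probes. A further 23 columns, headed as bead standard errors, were not used. The deposited series table holds the authors' processed intensity of the same arrays. Its ranks followed the scanner intensities (Spearman correlation 1 on the lowest and highest array, Pearson 0.958 to 1), its column medians ran from 4.44 to 4.55, and 26.6% of its values were below 0. Its columns also had close lower quartiles (-0.237 to -0.203), upper quartiles (50.6 in all) and 95% points (629 in all). It is therefore on a linear scale after background subtraction, with the columns brought close to each other at these points. Which step gave this is not given in the sources used here, and it served only as an alternative. GenomeStudio and Partek are named in the submitters' processing notes, with versions not given.

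The mean intensity of an array ran from 142.4 to 366.4 and the number of probes detected at a p-value under 0.05 from 10353 to 12654. Each probe was read on an average of 27 to 40.4 beads per array. The number of arrays limits the precision of each value. The table holds 25697 probes. The platform annotation gives 1 gene symbol for 23978 probes, several for 0 and none for 1719. Of the named probes, 23962 were found by Entrez identifier in a RefSeq gene table, and 0 symbols changed. Intensities were corrected for background with normexp, using the detection p-values to place the negative controls, with an offset of 16, then quantile-normalized and put on the log2 scale (limma 3.58.1 and version 1.17.8 of data.table in R 4.3.3). Probes with a detection p-value under 0.05 on at least 4 arrays were kept (13831, of which 13030 had a gene symbol), and the brightest probe stood for each gene, which left 9732 genes. The 6861 other named genes of the array were not tested. Where another kept probe of a named gene gave a clearly different value, the text says so. Correlations between arrays over these genes ran from 0.939 to 0.993, so no array was a copy of another.

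A linear model with the 5 groups was fitted to all 23 arrays (18 residual degrees of freedom) with limma's lmFit and eBayes. All adjusted p-values for genes are from this limma fit, adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. SE is the moderated standard error. The comparisons were KHR-N-/- with KHR, KHR-N+/- with KHR, KHR-N-/- with KHR-N+/-, KR-N-/- with KR-N+/-, KHR-N+/- with KR-N+/- and KHR-N-/- with KR-N-/-, and the interaction, which is the difference between the Notch1 effect (N-/- against N+/-) in KHR-type and KR-type tumours. Slide positions are not given in the files, so the model has no slide term. A gene not detected on any array of its dimmer group is given as "at least N-fold", with the dimmer group set at the lowest signal among detected probes of each array.

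Before the data were examined, 33 lists holding 578 gene entries were fixed. They cover keratinocyte states, Notch signalling, matrix proteases, epithelial-mesenchymal transition, cell cycle, p53, immune, hypoxia, Ras-ERK and Wnt genes, and markers of other cell types in the tissue. The array annotation held 524 of the entries and 390 were measured. Lists with at least 5 measured genes (28) were tested with limma's fry, which asks whether the genes of a list move, on balance, one way, and adjusted over the lists of a comparison. Camera with an estimated correlation, which compares a list with the other genes, was an alternative, as was camera with a preset correlation of 0.01. Salivary gland, B and plasma cell, Dendritic cell, and Nerve and Schwann cell markers had too few measured genes. Sex-linked genes were kept for values only.

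The text names genes by a rule also fixed beforehand. It takes Notch1, the 8 genes with the largest rise and the 8 with the largest fall among those that passed, the 5 with the smallest p where fewer than 5 passed, and up to 3 members with the smallest p of each list that passed. The same 3 are taken for Notch target genes, Suprabasal keratinocyte differentiation, Matrix proteases, Cell cycle and E2F target genes, and Skeletal muscle whether these pass or not. A gene named outside this rule is said to have been chosen after its values were seen.

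The alternatives were no background correction, scaling to a common median in place of quantile normalization, an offset of 50, the authors' processed values, no detection filter, a stricter filter (p under 0.01 on at least 12 arrays), each probe tested by itself, the replicate number as a block, only the groups of a comparison in the fit, array weights, eBayes with trend and robust settings, the mean of the Skeletal muscle list as a covariate, and each array left out in turn. After the data were seen, covariates for array intensity and for bead number were added, a block for 3 sets of arrays with differing bead numbers in table order (7, 8 and 8 arrays), and a fit without KHR replicate 5 and KHR-N+/- replicate 3. The model fit and the list test were tried on simulated data of 9732 genes with 50 genes changed at each size. Background correction, normalization and filtering were not part of this trial. The simulated noise was independent for each gene and array, without correlation between genes or outlying arrays, so the shares below hold for such noise only. For KHR-N-/- against KHR, 40% of changes of 0.5, 94% of changes of 1, 98% of changes of 2 and 96% of changes of -1 on the log2 scale were recovered, and 3.95% of the 177 calls were false. For KR-N-/- against KR-N+/- these shares were 50%, 94%, 100% and 90%, with 3.41% of 176 calls false. A shift of 0.4 of the cell cycle list was found in both, and of the 27 other lists 1 and 2 were called.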

Results

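Messenger RNA levels were compared between oral tumours of 2 types, KHR and KR, whose Notch1 gene was intact, present in 1 copy or absent. Notch1 encodes a receptor that drives differentiation in stratified epithelia when cleaved after contact with ligands on neighbouring cells. The arrays covered 5 KHR, 4 KHR-N+/-, 5 KHR-N-/-, 5 KR-N+/- and 4 KR-N-/- tumours. Signal differed between the groups before normalization. The mean array intensity was 260.5 ± 46.5 in KHR (SD, n = 5), 311.5 ± 37.4 in KHR-N+/- (SD, n = 4), 261.6 ± 29.0 in KHR-N-/- (SD, n = 5), 214 ± 87.2 in KR-N+/- (SD, n = 5) and 192.4 ± 53 in KR-N-/- (SD, n = 4). The number of detected probes was 11779 ± 540, 12360 ± 244, 12311 ± 235, 11218 ± 746 and 11596 ± 509 in the same order. Quantile normalization gives all arrays the same distribution, so every change below is relative to the other genes on the array.

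Group means of the Notch1 probe followed the labels. Its log2 intensity was 8.27 ± 0.38 in KHR (SD, n = 5), 6.80 ± 0.85 in KHR-N+/- (SD, n = 4), 5.67 ± 0.16 in KHR-N-/- (SD, n = 5), 7.72 ± 0.28 in KR-N+/- (SD, n = 5) and 6.02 ± 0.38 in KR-N-/- (SD, n = 4). The array carries 1 probe for the gene, and whether it lies in the deleted part is not given in the sources used here. The library labelled KHR-N+/- replicate 3 had a level of 5.68, inside the range of the KHR-N-/- arrays (5.40 to 5.80), and the comparisons that use KHR-N+/- tumours below include it under its label.

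**Figure D1:**
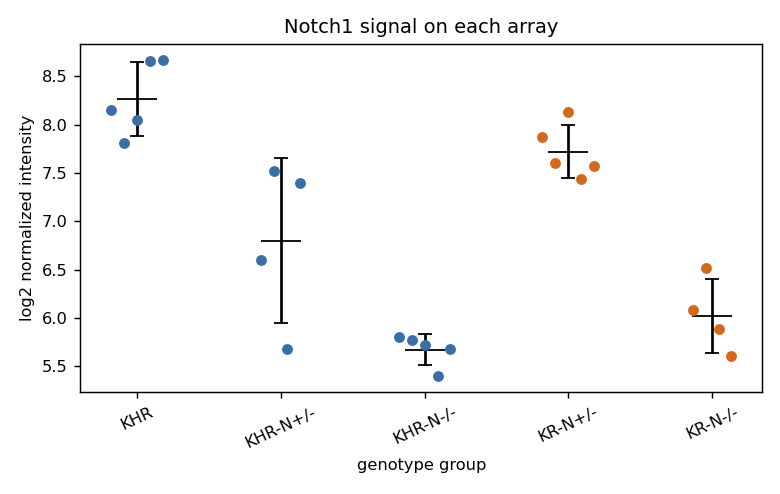
Log2 normalized intensity of the Notch1 probe (vertical axis) for each array in the 5 genotype groups (horizontal axis); points are arrays, and the bar with whiskers is the mean and SD. All 5 KHR-N-/- arrays lie between 5.40 and 5.80, and 1 KHR-N+/- array lies among them at 5.68.

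The first comparison asks what complete loss of Notch1 does in KHR tumours. In KHR-N-/- against KHR tumours Mmp13, a collagenase, was 7.81-fold higher (log2 2.97, SE 0.47, adjusted p = 0.000379), although its other probes gave 0.11 and 0.97. The stromelysins Mmp10 and Mmp3 were 6.32-fold and 5.71-fold higher (adjusted p = 0.000897 and 3.85e-05), with Mmp10 detected on 2 of 5 KHR arrays and its log2 difference running from 1.254 to 2.933 over the alternatives, and the gelatinase Mmp9 was 5.81-fold higher (log2 2.54, SE 0.43, adjusted p = 0.000729). The protease inhibitor genes Csta2 and Cstdc4 rose by 2.84 and 2.50 on the log2 scale. The hair-type keratin genes Krt34, Krt71 and Krt86 fell by 2.10, 2.01 and 1.92 (SE 0.58, 0.57 and 0.55), calls that passed in 10, 9 and 9 of 16 alternatives.

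Notch1 itself fell by 2.59 (SE 0.26, adjusted p = 5.2e-06). In all, 714 of 9732 genes passed, 445 higher and 269 lower in KHR-N-/-, and 150 of them by at least a log2 difference of 1. Prss35, a serine protease family member, and Fgfr1op2 rose by 2.63 and 2.27, but the other probe of Fgfr1op2 gave 0.12 and KHR replicate 5 (7.28) lay with the Notch1-modified tumours on this gene. Wfdc2, encoding a secreted protein with protease inhibitor domains, Klk14, a kallikrein, AA467197 and Krtap1-5 fell by 2.09, 1.75, 1.73 and 1.62. AA467197 passed in 11 of 16 alternatives. The call of Krtap1-5 passed in 9 of 16 alternatives (-3.126 to -0.633, detected on 1 of 5 KHR-N-/- arrays) and was lost in 14 of the 23 fits that left out 1 array.

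The Matrix proteases list rose as a group. Of its 24 measured members 10 rose, 0 fell and 14 did not pass, and 14 higher and 1 lower passed when adjusted over the list alone (fry adjusted p = 0.000438; adjusted p = 0.163 with an estimated correlation). Besides Mmp3, its leading members were Ctsk, a cysteine protease of bone-resorbing cells, at 1.81 and Mmp11 at 1.29 (detected on 1 of 5 KHR arrays; 0.393 to 1.521 over the alternatives). Fibroblast and matrix genes rose with it: 12 of 18 were higher and 0 lower, 14 higher when adjusted over the list alone (fry adjusted p = 0.000117; adjusted p = 0.0646 with an estimated correlation). The fibrillar collagen genes Col5a1 and Col1a2 rose by 1.79 and 1.65, and the growth factor receptor Pdgfra by 1.28. In the Epithelial-mesenchymal transition list 6 of 18 rose, 7 when adjusted over the list alone, among them the collagen cross-linking enzyme Lox (1.38), the matrix protein Tgfbi (1.22) and the transcription factor Twist2 (1.20), with a fry adjusted p = 0.00896 (adjusted p = 0.279 with an estimated correlation). The mean log2 level of the Fibroblast and matrix list was 6.35 ± 0.40 in KHR (SD, n = 5) and 7.39 ± 0.24 in KHR-N-/- (SD, n = 5). KHR replicate 5 was at 7.045, close to the lowest KHR-N-/- array (7.091), and the other KHR arrays were at 6.048 to 6.356. It was also the highest KHR array on the Epithelial-mesenchymal transition (6.67 against 5.994 to 6.299), Matrix proteases (6.506 against 5.948 to 6.145) and Basal keratinocyte (9.313 against 8.811 to 8.965) lists.

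Skeletal muscle markers moved the same way as these groups. Their mean log2 level was 6.67 ± 0.19 in KHR (SD, n = 5) and 7.38 ± 0.15 in KHR-N-/- (SD, n = 5). Of 19 members 13 rose and 0 fell, and 14 higher and 1 lower passed when adjusted over the list alone (fry adjusted p = 0.0065; adjusted p = 0.279 with an estimated correlation). The calcium pump Atp2a1, the fast troponin Tnnc2 and the myosin Myh1 rose by 1.41, 1.22 and 1.16, with 0.02 for the other probe of Myh1. In the Mast cell list 3 of 6 rose, 4 when adjusted over the list alone (fry adjusted p = 0.0071; adjusted p = 0.279 with an estimated correlation). The mast cell proteases Tpsb2, Cpa3 and Cma1 were at 0.82, 0.76 and 0.63, and 1 other probe of Cpa3 gave -0.14. Tpsb2 and Cma1 were detected on 2 and 1 of 5 KHR arrays, and ran from 0.221 to 0.998 and from 0.16 to 0.754 over the alternatives. In the Macrophage and monocyte list 4 of 12 rose, 6 when adjusted over the list alone, with the scavenger receptors Mrc1 (1.01) and Cd163 (0.69) and the complement gene C1qb (0.80) in front (fry adjusted p = 0.0224; adjusted p = 0.364 with an estimated correlation).

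The Basal keratinocyte list includes genes that attach epithelium to its basement membrane. Of its 13 members 3 rose, 4 when adjusted over the list alone (fry adjusted p = 0.0184, and adjusted p = 0.279 by camera with an estimated correlation). The integrin Itga6, the hemidesmosome collagen Col17a1 and the cadherin Cdh3 were at 1.01, 0.91 and 0.49. Of 20 p53 target genes 3 rose, and the same number when adjusted over the list alone (fry adjusted p = 0.0184; adjusted p = 0.364 with an estimated correlation), with Bbc3, which promotes cell death, at 0.63, Zmat3 at 0.53 and the DNA polymerase gene Polk at 0.43; other probes of Bbc3 gave -0.06 and 0.09. Hypoxia and glycolysis genes rose in 4 of 16 members, 7 when adjusted over the list alone, led by Adm (0.75), the hexokinase Hk2 (0.68) and the carbonic anhydrase Car9 (0.67), with a fry adjusted p = 0.0372 (adjusted p = 0.364 with an estimated correlation) that passed in 7 of 15 alternatives and in 17 of the 23 fits that left out 1 array. The Bone and cartilage list passed upward (fry adjusted p = 0.0184; adjusted p = 0.435 with an estimated correlation) although its median was -0.01 and its mean 0.35, because Ctsk alone of its 5 members rose, also when adjusted over the list alone, while Comp and Acp5 were at -0.19 and 0.14.

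Notch target genes as a group did not pass (fry adjusted p = 0.192). Of 6 members 2 fell, the feedback regulator Nrarp by 0.66 (SE 0.15, adjusted p = 0.00646) and the receptor Notch3 by 0.30 (SE 0.09, adjusted p = 0.0482, passed in 7 of 16 alternatives), and Hey1 was at 0.39 (adjusted p = 0.113); 1 higher and 2 lower passed when adjusted over the list alone. Suprabasal differentiation genes did not pass (fry adjusted p = 0.755). The cornified envelope gene Ivl alone of its 30 members rose, by 1.82, while Sprr3 and Lce3a were at -1.43 and -0.85 (adjusted p = 0.0684 and 0.0623). Cell cycle genes did not pass either (fry adjusted p = 0.539), with 3 of 30 lower, Cdc6, Ccne1 and Mcm5 by 0.48, 0.47 and 0.46, and 1 higher and 3 lower when adjusted over the list alone. The count of 714 genes became 165 (149 higher, 16 lower) with median scaling, which put the median of all genes at 0.12, 385 with only both groups in the fit, 153 with the muscle covariate, 2230 with array weights and 1254 without KHR replicate 5 and KHR-N+/- replicate 3. Without KHR replicate 2 or KHR-N-/- replicate 5 it was 461 and 469, and without KHR replicate 4 or 5 it was 1169 and 1331. The count of 10 lists became 5 with the muscle covariate and 4 with median scaling or with only both groups. The Macrophage and monocyte, p53 target and Bone and cartilage lists passed in 12 of 15, 12 of 15 and 10 of 14 alternatives.

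The next comparison asks what loss of 1 copy does. In KHR-N+/- tumours Notch1 fell by 1.47 (SE 0.27, adjusted p = 0.0066) against KHR, and 122 genes passed, 80 higher and 42 lower. The genes with the largest rises were Fgfr1op2 (4.95-fold, SE 0.34 on the log2 scale, adjusted p = 0.00297), the actin-severing Cfl1 (3.37-fold, SE 0.27, adjusted p = 0.00354), the retinoid-binding Rbp7 (3.16-fold, SE 0.23, adjusted p = 0.00168) and Ivl (2.95-fold, SE 0.34, adjusted p = 0.021). Adh7, an alcohol dehydrogenase of surface epithelia, Cstdc4, Mmp3 and the secreted peroxidase Gpx3 rose by 1.53, 1.52, 1.49 and 1.45. The matrix protein Spon2, Wfdc2, Guca1a and Anxa4 fell by 1.36, 1.19, 1.17 and 1.17, and the eosinophil-attracting chemokine Ccl11, the transcription factor Sox21 and Tmem87a by 1.16, 1.14 and 1.11. Cstdc4, Mmp3 and Ivl passed in 10, 11 and 11 of 16 alternatives and were lost in 5, 5 and 4 of the 23 fits that left out 1 array. The call of Wfdc2 passed in 5 of 16 alternatives and was lost in 14 of the 23 fits that left out 1 array. On Fgfr1op2, Cfl1, Anxa4, Guca1a and Tmem87a, KHR replicate 5 lay with the other groups and apart from KHR replicates 1 to 4, and the other probe of Fgfr1op2 gave 0.20.

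None of the 28 lists passed (0 by fry, with 4 at an unadjusted p under 0.05, and 0 by camera with an estimated correlation). In the Matrix proteases list (fry adjusted p = 0.254) Mmp3 and Ctsk (1.22) rose, 4 when adjusted over the list alone, and Mmp13 was at 1.86 (adjusted p = 0.0737). In the Skeletal muscle list (fry adjusted p = 0.254) Atp2a1 and Myh1 rose by 1.13 and 0.92, 7 when adjusted over the list alone, and Tnnc2 was at 0.74 (adjusted p = 0.142). The other probe of Myh1 gave -0.02. Atp2a1 and Myh1 passed in 12 and 8 of 16 alternatives and were lost in 5 and 6 of the 23 fits that left out 1 array. The muscle list's mean was 7.06 ± 0.20 in KHR-N+/- (SD, n = 4), between the KHR and KHR-N-/- values. For Notch target genes the fry adjusted p was 0.997, with Hey1 at 0.30, Nrarp at -0.30 and Hes1 at -0.12 (adjusted p = 0.504, 0.502 and 0.906). Suprabasal genes (0.969) had Ivl higher, and Casp14 and Krt4 at 0.51 and 1.11 (adjusted p = 0.299 and 0.458). Cell cycle genes (0.991) had Mcm6, Cdkn2a and Nusap1 at 0.61, 0.56 and 0.43 (adjusted p = 0.12, 0.388 and 0.358). With only both groups in the fit 0 genes passed, with median scaling 28 (26 higher, 2 lower; median of all genes 0.29), without the detection filter 70, with the muscle covariate 55 and with array weights 891. The count was 53, 48, 54, 212 and 254 without KHR replicates 1 to 5 in turn, and 70, 44 and 41 without KHR-N+/- replicates 1, 2 and 3.

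Loss of the remaining copy was addressed within KHR-type tumours by KHR-N-/- against KHR-N+/-. Only 10 genes passed, 7 higher and 3 lower in KHR-N-/-. Slitrk5, encoding a neuronal membrane protein, rose by 1.63 (SE 0.29, adjusted p = 0.0299), the signalling ligand Wnt3a by 1.07 (SE 0.19, adjusted p = 0.0299), Col17a1 by 0.97 (SE 0.18, adjusted p = 0.0302) and the ubiquitin ligase Trim32 by 0.91 (SE 0.16, adjusted p = 0.0299). Ctnnal1, the potassium channel Kcnh1 and the pigment enzyme Dct rose by 0.91, 0.87 and 0.74. The retinoic acid-producing enzyme Aldh1a3 fell by 1.14, and Noct and Acp6 by 0.77 and 0.68. Ctnnal1, Kcnh1 and Noct passed in 5, 6 and 7 of 16 alternatives and were lost in 15, 18 and 16 of the 23 fits that left out 1 array, and Dct passed in 8 of 15 alternatives. The 6 other genes passed in 10 to 12 of 16 alternatives and were lost in 6 or 7 of those fits. Dct was near background in KHR-N+/- (4.17 to 4.21), detected on 1 of 4 arrays, and only replicate 3 was higher at 5.00. The difference of Dct ran from 0.207 to 0.987 over the alternatives. The other probe of Trim32 gave 0.25. Notch1 was at -1.13 (SE 0.27, adjusted p = 0.122) and did not pass. Without the library labelled KHR-N+/- replicate 3 it was at -1.50 and passed.

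Basal keratinocyte genes rose in this comparison (fry adjusted p = 0.0144; adjusted p = 0.0381 with an estimated correlation). Of 13 members 1 rose, Col17a1, and 6 when adjusted over the list alone, with the laminin Lamb3 and the integrin Itgb4 at 0.96 and 0.87 (adjusted p = 0.196 and 0.195 over all genes). Fibroblast and matrix genes rose as a list as well (fry adjusted p = 0.0144; adjusted p = 0.0381 with an estimated correlation), with 0 of 18 passing over all genes and 13 when adjusted over the list alone. Both list calls were lost without KHR-N+/- replicate 1 (adjusted p = 0.0956), which stood apart on the Fibroblast and matrix list, and without KHR-N-/- replicate 5 (adjusted p = 0.0554). Col5a1, Col1a2 and Fstl1 were at 1.09, 0.92 and 0.79 (adjusted p = 0.171, 0.196 and 0.198). The Matrix proteases list did not pass (0.0589), with 7 members higher when adjusted over the list alone and Mmp10, Mmp11 and Mmp2 at 1.91, 0.83 and 0.64 (adjusted p = 0.162, 0.0507 and 0.223). Notch target genes (0.295) had Notch3, Nrarp and Hes1 at -0.35, -0.36 and -0.17 (adjusted p = 0.206, 0.524 and 0.935). Skeletal muscle genes (0.295) had Mylpf, Myl1 and Mb at 0.86, 0.61 and 0.55 (adjusted p = 0.209, 0.412 and 0.486). Suprabasal genes (0.604) had Lce3a, Cnfn and Tgm1 at -0.90, -0.53 and -0.42, and cell cycle genes (0.519) had Ccne1, Rrm1 and Mcm5 at -0.46, -0.31 and -0.24, none passing. The count of 10 was 0 with no background correction, with median scaling (median of all genes -0.15), without the detection filter and with only both groups, 6 with the authors' values, 5 and 4 with the muscle and intensity covariates, 17 with trend and robust settings, 19 with the bead covariate, 81 without both doubted arrays (KHR replicate 5 and KHR-N+/- replicate 3) and 265 with array weights. It was 0 without KHR-N+/- replicate 1, 2 or 4 or KHR-N-/- replicate 2, 4 or 5, 6 and 18 without KHR-N-/- replicates 3 and 1, and 36, 31 and 46 without KHR replicate 4, KHR replicate 5 and KHR-N+/- replicate 3.

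**Figure D2:**
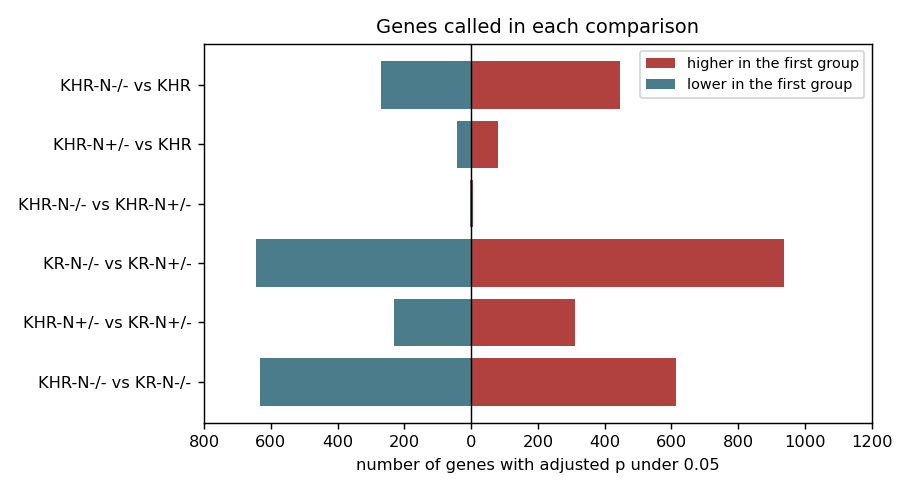
Number of genes with an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), higher in the first-named group to the right and lower to the left. Between KHR-N-/- and KHR-N+/- 10 genes passed, and between KR-N-/- and KR-N+/- 1581.

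The same contrast in KR tumours gave many more calls. In KR-N-/- against KR-N+/- tumours AA467197 fell by 4.84 (SE 0.51, adjusted p = 9.27e-06), the platelet and neutrophil-attracting chemokine Ppbp by 4.17 (SE 1.01, adjusted p = 0.00791), the membrane protein Psca fell by 3.53 (SE 0.58, adjusted p = 0.000747) and the cornified envelope gene Sprr3 by 3.31 (SE 0.50, adjusted p = 0.000455). The lipid enzyme Fa2h, the raft protein Mal, the tight junction gene Cldn17 and 2300002M23Rik fell by 2.67, 2.62, 2.59 and 2.22. The collagen genes Col1a1, Col6a1 and Col26a1 rose by 2.37, 1.97 and 1.90 (SE 0.45, 0.40 and 0.22), Slitrk5 by 2.12, Csta2 by 2.06, Crabp1, which binds retinoic acid, by 1.73, the hyaluronan synthase Has3 by 1.72 and Prss35 by 1.61. Col26a1 was detected on 1 of 5 KR-N+/- arrays, and Ppbp and Mal on 2 of 4 KR-N-/- arrays. Over the alternatives Col26a1 ran from 0.636 to 2.237, Ppbp from -4.497 to -2.264 and Mal from -2.893 to -1.135.

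Notch1 fell by 1.70 (SE 0.27, adjusted p = 0.000711) in KR-N-/- against KR-N+/-. Of all genes 1581 passed, 936 higher and 645 lower, 188 of them by at least a log2 difference of 1. Basal keratinocyte genes rose in 7 of 13 members and fell in 0, 9 higher when adjusted over the list alone (fry adjusted p = 0.000595; adjusted p = 0.257 with an estimated correlation), among them Lamb3 (1.29), Col17a1 (0.88) and Cdh3 (0.62). Stress and wound keratinocyte genes fell in 8 of 14 members, 9 when adjusted over the list alone (fry adjusted p = 0.000595; adjusted p = 0.178 with an estimated correlation). S100a7a, S100a9 and S100a8, which encode calcium-binding proteins of inflamed epithelium and neutrophils, fell by 1.87, 1.09 and 1.09. Suprabasal differentiation genes fell in 8 of 30 members, and in 8 when adjusted over the list alone, including Sprr3, Lce3a by 1.62 and the peptidase Klk7 by 0.92. That list's test (fry adjusted p = 0.047; adjusted p = 0.397 with an estimated correlation) passed in 9 of 15 alternatives and in 8 of the 23 fits that left out 1 array.

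Fibroblast and matrix genes were higher in KR-N-/- tumours in 9 of 18 members, 10 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.0119; adjusted p = 0.397 with an estimated correlation), with the receptor Pdgfrb at 1.02 and Col5a1 at 1.47 beside Col1a1. Their mean log2 level was 6.60 ± 0.16 in KR-N+/- (SD, n = 5) and 7.26 ± 0.14 in KR-N-/- (SD, n = 4). In the Matrix proteases list 6 of 24 rose, and 6 when adjusted over the list alone (fry adjusted p = 0.0119; adjusted p = 0.397 with an estimated correlation), led by Mmp11 (1.24), the membrane-bound Mmp14 (1.16) and Adamts4 (0.68). In the Epithelial-mesenchymal transition list 6 of 18 rose, 10 when adjusted over the list alone (fry adjusted p = 0.00869; adjusted p = 0.397 with an estimated correlation), with Thy1, Twist2 and Tgfbi at 1.09, 1.05 and 1.01. Pdgfrb, Mmp11 and Adamts4 were detected on 1, 2 and 1 of 5 KR-N+/- arrays, and ran from 0.298 to 1.154, 0.36 to 1.387 and 0.176 to 0.749 over the alternatives. Endothelium genes rose in 3 of 13, the receptor Tek (0.82), Robo4 (0.77) and Cdh5 (0.46), and 3 when adjusted over the list alone (fry adjusted p = 0.0338; adjusted p = 0.462 with an estimated correlation). Leaving out 1 array kept the list's call in 16 of 23 fits and lost Cdh5 in 14 and Robo4 in 10, and Cdh5 passed in 8 of 15 alternatives (0.14 to 0.762, detected on 1 of 5 KR-N+/- arrays). Wnt target genes rose in 3 of 11, with Dkk3 at 1.16, Wnt10a at 0.83 and Axin2 at 0.68, and 3 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.00572; adjusted p = 0.397 with an estimated correlation).

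Cell cycle and E2F target genes rose in 11 of 30 members and fell in 0, 13 higher when adjusted over the list alone (fry adjusted p = 0.0179; adjusted p = 0.455 with an estimated correlation). The mitotic motor Kif11, the anaphase activator Cdc20 and the replication helicase subunit Mcm5 rose by 0.80, 0.66 and 0.53, and 1 other probe of Cdc20 gave -0.19. Notch receptors, ligands and cofactors passed upward with 1 of 15 members higher, the ligand Jag2 at 0.68, and 4 when adjusted over the list alone (fry adjusted p = 0.0128; adjusted p = 0.593 with an estimated correlation); Maml1 and Mfng were at 0.39 and 0.34 (adjusted p = 0.0504 and 0.0527). MHC class I genes fell in 2 of 11, and in 2 when adjusted over the list alone, B2m by 1.31 and H2-T23 by 1.27, with H2-D1 at -0.36 (fry adjusted p = 0.0338; adjusted p = 0.397 with an estimated correlation; kept in 16 of the 23 fits that left out 1 array). Adipocyte genes fell in 2 of 6, and in 2 when adjusted over the list alone, Cidea by 1.45 and Scd1 by 1.00, with Plin4 at -0.37 (fry adjusted p = 0.000322; adjusted p = 0.257 with an estimated correlation). The Neutrophil list fell (fry adjusted p = 0.0179; adjusted p = 0.397 with an estimated correlation) through S100a8 and S100a9, which also belong to the stress list, whereas Mmp9 rose by 1.33, and the same 1 higher and 2 lower passed when adjusted over the list alone. The call of Mmp9 passed in 5 of 16 alternatives and was lost in 15 of the 23 fits that left out 1 array.

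The Skeletal muscle list did not pass in KR tumours (fry adjusted p = 0.398), with its mean at 8.07 ± 0.33 in KR-N+/- (SD, n = 5) and 7.80 ± 0.43 in KR-N-/- (SD, n = 4). Ckm and Mb fell by 0.91 and 0.65, and Actn3 rose by 0.44, with 0.10 for its other probe. The call of Mb passed in 6 of 16 alternatives and was lost in 15 of the 23 fits that left out 1 array. Notch target genes did not pass (fry adjusted p = 0.665), with Hes1 at -0.46, Nrarp at -0.42 and Hes6 at 0.36 (adjusted p = 0.124, 0.0699 and 0.182), and both other probes of Hes6 gave -0.01 and -0.03. With median scaling only 3 genes passed (1 higher, 2 lower) and 0 lists. Without KR-N-/- replicate 2 the count was 897.

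**Figure D3:**
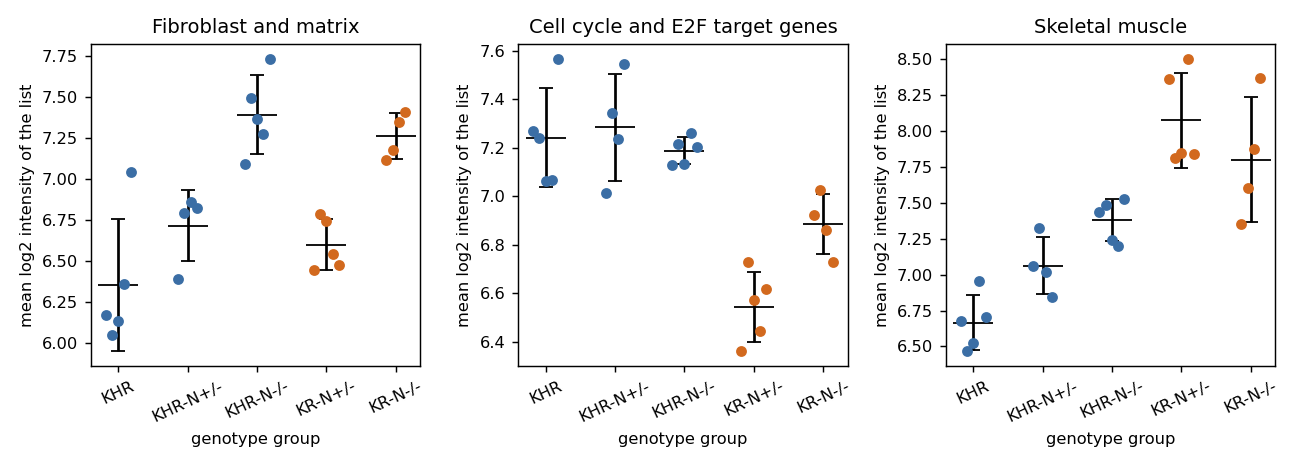
Mean log2 intensity of the measured members of 3 fixed lists (vertical axes) for each array in the 5 genotype groups (horizontal axes); points are arrays, and the bar with whiskers is the mean and SD. The Fibroblast and matrix mean is 7.39 in KHR-N-/- and 7.26 in KR-N-/-, the cell cycle mean is lowest in KR-N+/- at 6.54, and the Skeletal muscle mean is highest there at 8.07.

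Whether the Notch1 effect differed between tumour types was tested directly as an interaction in limma. No gene passed (0 of 9732, smallest adjusted p = 0.334), while 793 had an unadjusted p under 0.05 where 487 would by chance, and 0 of 28 lists passed by fry (4 at an unadjusted p under 0.05) or by camera with an estimated correlation. The 5 genes with the smallest p, none of which passed (adjusted p = 0.334), were the arginine methyltransferase Prmt1 at -1.69 (SE 0.40), Col26a1 at -1.36 (SE 0.30), the linker histone H1f10 at -1.12 (SE 0.25), Mcm5 at -0.78 (SE 0.16) and the urate transporter Slc2a9 at -0.71 (SE 0.17). Notch1 was at 0.58 (SE 0.38, adjusted p = 0.762). Cell cycle genes had a median of -0.47 (fry adjusted p = 0.214), with Ccne1 and Kif11 at -0.75 and -0.92, and Skeletal muscle genes 0.59 (fry adjusted p = 0.249), with Mylpf, Mb and Ckm at 1.27, 1.19 and 1.12. Suprabasal genes (0.643) had Sprr3, Krt13 and Klk7 at 2.39, 1.17 and 0.63, Notch target genes (0.846) had Hes1, Notch3 and Hes6 at 0.30, -0.18 and -0.27, and Matrix proteases (0.894) had Adamts4, Mmp2 and Mmp11 at -0.49, 0.49 and -0.42. The larger count in KR tumours is therefore not shown to be a larger effect.

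All 10 genes that passed between KHR-N-/- and KHR-N+/- also passed between KR-N-/- and KR-N+/- in the same direction, 7 higher (0.673 by independent lists) and 3 lower (0.199 by independent lists). These comparisons share no array, but each gene has the same estimate of spread in every comparison of the fit. Counts by independent lists, here and below, may therefore be too low. Slitrk5 was at 1.63 and 2.12, Aldh1a3 at -1.14 and -1.74 and Col17a1 at 0.97 and 0.88. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.681 and rho = 0.571. For KHR-N-/- against KHR and KR-N-/- against KR-N+/-, 158 genes were higher in both (42.8 by independent lists), 73 lower in both (17.8 by independent lists) and 14 opposite, with r = 0.479 and rho = 0.38.

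The tumour types were compared at each Notch1 genotype. With 1 copy, KHR-N+/- tumours had more messenger of 2 meiosis genes than KR-N+/-, with Stag3, a cohesin subunit of meiotic chromosomes, 8.20-fold higher (log2 3.04, SE 0.17, adjusted p = 6.74e-11) and Zcwpw1, a reader of meiotic histone marks, 5.13-fold higher (log2 2.36, SE 0.15, adjusted p = 2.28e-10). Their KR-N+/- levels were close to background, with each gene detected on 1 of 5 arrays, so the size of the folds depends on how background is handled. The log2 difference ran from 1.275 without background correction to 3.505 with median scaling for Stag3 and from 0.888 to 2.816 for Zcwpw1, and both calls were kept in 16 of 16 alternatives. The muscle calcium buffer Pvalb fell by 3.07 on the log2 scale (SE 0.29, adjusted p = 5.2e-07). The intermediate filament gene Nes, the protease inhibitor genes Stfa2, Csta3 and Spink7, Ivl and the replication-linked Fam111a rose by 2.09, 1.88, 1.88, 1.78, 1.59 and 1.51. Serpinb6d, Slitrk5, Clec2e, Spon2, Fa2h, the muscle respiratory subunit Cox8b and the creatine kinase Ckm fell by 1.77, 1.71, 1.69, 1.65, 1.61, 1.55 and 1.43, but the other probe of Clec2e gave 0.02. Nes was detected on 2 of 5 KR-N+/- arrays and ran from 0.826 to 2.523 over the alternatives.

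In that comparison 542 genes passed, 311 higher and 231 lower. Cell cycle and E2F target genes rose in 21 of 30 members and fell in 0, 24 higher when adjusted over the list alone (fry adjusted p = 1.93e-05; adjusted p = 0.0292 with an estimated correlation). Cdc20, Mcm5 and the cyclin Ccne1 rose by 1.37, 1.11 and 0.92. The list's mean log2 level was 7.28 ± 0.22 in KHR-N+/- (SD, n = 4) and 6.54 ± 0.15 in KR-N+/- (SD, n = 5). Its call was kept in 14 of 15 alternatives and lost with the muscle covariate (fry adjusted p = 0.0687). Skeletal muscle markers moved the other way in the same tumours, with 14 of 19 lower and 0 higher, 18 lower when adjusted over the list alone (fry adjusted p = 0.000589; adjusted p = 0.0832 with an estimated correlation), and Eno3 fell by 1.07. The Adipocyte list fell (fry adjusted p = 0.0178; adjusted p = 0.581 with an estimated correlation) with 0 of 6 members passing over all genes and 1 lower when adjusted over the list alone, and Plin4, Scd1 and Pparg at -0.56, -0.44 and -0.31 (adjusted p = 0.0557, 0.206 and 0.314). That list passed in 8 of 14 alternatives.

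Notch1 fell by 0.92 in KHR-N+/- against KR-N+/- (SE 0.27, adjusted p = 0.0465), a call that passed in 5 of 16 alternatives and became -0.55 without the library labelled KHR-N+/- replicate 3. Notch target genes did not pass (fry adjusted p = 0.413), with Hes1, Notch3 and Dtx4 at -0.34, -0.15 and 0.11. Suprabasal genes (0.749) had Ivl higher and Sprr2d and Lor at 0.61 and -0.37, and Matrix proteases (0.631) had Mmp3 higher by 1.35 and Ctsk and Mmp11 at 0.68 and 0.46. The count of 542 was 12 with the muscle covariate, 108 with the intensity covariate, 1080 with array weights and 4543 (4527 higher, 16 lower) with median scaling, which put the median of all genes at 0.65. Without KHR-N+/- replicates 2 and 3 and KR-N+/- replicate 4 it was 354, 307 and 314, and without KHR replicate 4 it was 870.

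Without Notch1, KHR-N-/- tumours again exceeded KR-N-/- in Stag3 (7.66-fold, log2 2.94, SE 0.17, adjusted p = 1.38e-10) and Zcwpw1 (3.85-fold, log2 1.94, SE 0.15, adjusted p = 1.35e-08). They were detected on 2 and 3 of the 4 KR-N-/- arrays, and the log2 differences ran from 1.299 to 3.219 and from 0.726 to 2.241 over the 16 alternatives, all of which kept the calls. Over all arrays Stag3 was 6.71 to 7.74 in the 14 KHR-type tumours and 4.2 to 4.78 in the 9 KR-type tumours. Ivl was 6.14-fold higher (SE 0.34 on the log2 scale, adjusted p = 6.7e-05), and AA467197, the lysozyme family gene Lyg1, the iron-scavenging lipocalin Lcn2, the adenosine deaminase Ada and Spink7 rose by 2.48, 2.38, 1.80, 1.79 and 1.78. Pvalb fell by 2.49 (SE 0.29, adjusted p = 1.51e-05), Slitrk5 fell by 2.21, the clock-output factor Dbp by 1.41, and Zxda, Spon2, Col26a1, Matn4 and Erich5 by 1.37, 1.35, 1.35, 1.24 and 1.20.

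Of all genes 1247 passed between KHR-N-/- and KR-N-/-, 614 higher and 633 lower. Neutrophil genes rose in 3 of 10 members, and in 3 when adjusted over the list alone (fry adjusted p = 0.000288; adjusted p = 0.116 with an estimated correlation). They were S100a8 (1.39), S100a9 (1.35) and Retnlg, which was not detected in KR-N-/- and was at least 1.7-fold higher in KHR-N-/- (adjusted p = 0.00519). Stress and wound keratinocyte genes rose in 5 of 14, 6 when adjusted over the list alone, with the defensin Defb14 at 1.45 beside the S100 genes (fry adjusted p = 0.0112; adjusted p = 0.35 with an estimated correlation). Cytokine and chemokine genes rose in 3 of 18, 6 when adjusted over the list alone: Il1a (1.14), Cxcl1 (0.74) and Ccl3, at least 1.26-fold higher (fry adjusted p = 0.0125; adjusted p = 0.35 with an estimated correlation). Ccl3 and Cxcl1 passed in 9 of 15 and 10 of 16 alternatives and were lost in 12 and 6 of the 23 fits that left out 1 array, and Il1a, detected on 2 of 4 KR-N-/- arrays, ran from 0.342 to 1.342. Hypoxia and glycolysis genes rose in 7 of 16 and fell in 1, 8 and 2 when adjusted over the list alone, with Ndrg1, Hk2 and Pdk1 at 1.23, 0.76 and 0.55 (fry adjusted p = 0.0112; adjusted p = 0.35 with an estimated correlation).

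Cell cycle genes rose in 9 of 30 and fell in 1, 13 and 1 when adjusted over the list alone, with Cdk1, Cdc20 and Rrm1 at 1.23, 0.71 and 0.67 (fry adjusted p = 0.03; adjusted p = 0.379 with an estimated correlation). MHC class I genes rose in 3 of 11, and in 3 when adjusted over the list alone: B2m (1.33), H2-T23 (0.90) and H2-D1 (0.75), with a fry adjusted p = 0.03 (adjusted p = 0.379 with an estimated correlation). The Macrophage list rose (fry adjusted p = 0.03; adjusted p = 0.367 with an estimated correlation) with Cd14 (0.69) and Cd163 (0.56) of 12 members passing, 3 when adjusted over the list alone, and Mrc1 at 0.66. Cd14 and Cd163 each passed in 11 of 16 alternatives and were lost in 7 and 15 of the 23 fits that left out 1 array. The Bone and cartilage list rose through Ctsk (0.76) alone of 5 members, also when adjusted over the list alone, with Bglap and Acp5 at 0.52 and 0.22 (fry adjusted p = 0.03; adjusted p = 0.367 with an estimated correlation), and the Mast cell list through Hdc (1.05) and Cpa3 (0.63) of 6, with Tpsb2 at 0.39 and the same 2 higher when adjusted over the list alone (fry adjusted p = 0.0495; adjusted p = 0.433 with an estimated correlation). Cpa3 was detected on 2 of 4 KR-N-/- arrays and ran from 0.179 to 0.856 over the alternatives, its other probes gave 0.46 and -0.21, and the Mast cell list passed in 6 of the 23 fits that left out 1 array. Notch receptors, ligands and cofactors fell (fry adjusted p = 0.036; adjusted p = 0.55 with an estimated correlation) with Maml3 lower (-0.59) and Notch4 and Dll1 at -0.72 and 0.38, and the call was kept in 15 of the 23 fits that left out 1 array.

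Notch1 was at -0.35 (adjusted p = 0.433) between KHR-N-/- and KR-N-/-. Of the Notch target genes (fry adjusted p = 0.113) Notch3 fell by 0.33, and Hes6 and Hey1 were at -0.36 and -0.17. Suprabasal genes did not pass as a list (0.116), with 5 of 30 higher and 12 when adjusted over the list alone, among them Cnfn (1.27) and Sprr2d (1.15). Skeletal muscle genes did not pass (0.0849), with Pvalb and Actn3 lower, the latter at -0.90, and Mybpc2 at -0.40. Matrix proteases did not pass (0.594), with Mmp3 and Ctsk higher by 1.07 and 0.76 (each passed in 12 of 16 alternatives) and Ctsb lower (-0.41). The count of 1247 was 290 with median scaling (287 higher, 3 lower; median of all genes 0.39), 334 and 506 with the intensity and muscle covariates, 2102 with only both groups and 2265 with array weights. It was 798, 686 and 696 without KR-N-/- replicates 1, 2 and 4, and 829 and 826 without KHR-N-/- replicates 3 and 4.

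Both comparisons of tumour type shared calls, with 139 genes higher in both (19.6 by independent lists), 112 lower in both (15 by independent lists) and 0 opposite, and r = 0.623 and rho = 0.585 across genes. They have no array in common but share the estimate of spread of each gene. Stag3, Zcwpw1, Ivl and Spink7 were higher in both and Pvalb, Slitrk5 and Spon2 lower in both, and under median scaling Slitrk5 and Spon2 kept their sign and lost their calls.

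Some lists passed in no comparison. The smallest fry adjusted p was 0.116 for Interferon response genes, 0.131 for MHC class II presentation, 0.413 for Ras-ERK output genes, 0.277 for Smooth muscle and pericyte, 0.508 for T cell, 0.134 for NK cell and cytotoxic and 0.236 for Erythroid markers. Xist, Kdm5d and Uty, which are sex-linked, had group means between 4.30 and 4.99 in the 5 groups. In that order they were detected on 1, 4 and 4 of 5 KHR arrays, 3, 1 and 3 of 4 KHR-N+/- arrays and 3, 2 and 2 of 5 KHR-N-/- arrays. For KR-N+/- these counts were 2, 3 and 1 of 5, and for KR-N-/- 2, 2 and 1 of 4. Signals this low do not settle the sex of the animals, and a difference in sex between groups was not tested.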

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

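The tests of the 3 patterns weighed here were chosen after their results were seen, except the test on further germline genes, which was fixed before its result was seen, and the counts over other splits of the arrays were planned.

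Of 542 groups examined for the genes and lists named, 39 held 1 array far from the others, which is 7.2% where chance sets about 1 in 20 groups apart. The value given is the gap to the nearest array of the group divided by the group's range. KHR replicate 5 and KR-N-/- replicate 4 had the most such values, 6 each. Over all 9732 genes it was KHR replicate 4 that stood apart most often, on 571 genes, 128 of them by at least a log2 of 1, against 212 and 47 for KHR replicate 5. Its mean was 7.501 for the MHC class II presentation list and 5.461 for the T cell list, where the other KHR arrays had 6.162 to 6.519 and 4.708 to 4.802. No explanation of this array was tested.

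The genes on which KHR replicate 5 stood apart from the other KHR arrays were Guca1a (4.87 against 6.42 to 6.47, 0.968), Anxa4 (0.889), Fgfr1op2 (7.28 against 4.55 to 4.95, 0.852), Col5a1 (8.56 against 6.95 to 7.23, 0.825), Tmem87a (0.791) and Cfl1 (0.788). KHR replicate 4 stood apart on Hes1 (6.2 against 7.39 to 7.83, 0.729). KHR-N+/- replicate 3 stood apart on Dct (0.95), Mmp3 (8.63 against 7.31 to 7.45, 0.898) and Trim32 (0.87), replicate 1 on Mmp11 (0.942) and the Fibroblast and matrix list (0.859), and replicate 4 on Kcnh1 (0.901) and Krt4 (9.44 against 10.76 to 11.02, 0.834). KHR-N-/- replicate 1 stood apart on Krt86 (0.908), Car9 (0.788) and the Hypoxia and glycolysis list (0.745), replicate 3 on Defb14 (0.733) and the Bone and cartilage list (0.864), and replicate 5 on Col26a1 (5.91 against 4.37 to 4.81, 0.712).

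Among KR-N+/- arrays, replicate 1 stood apart on Ccne1 (0.716) and Dtx4 (0.752), replicate 2 on Adamts4 (0.719) and Lor (0.756), replicate 3 on Col26a1 (0.925), replicate 4 on Pparg (0.826) and Slitrk5 (0.799), and replicate 5 on Mmp2 (0.915), S100a7a (0.87) and Spon2 (0.714). Among KR-N-/- arrays, replicate 1 stood apart on Prmt1 (9.73 against 10.83 to 11.03, 0.851), replicate 2 on Klk7 (0.981) and Tek (0.867), and replicate 4 on S100a7a (0.932), Axin2 (0.906), Zcwpw1 (0.9), Cd14 (0.882), the Notch receptors, ligands and cofactors list (0.877) and Hes6 (0.85).

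On 10 genes KHR replicates 1 to 4 lay apart, by at least 0.5 on the log2 scale, from KHR replicate 5 and all arrays of the other groups, and all 10, among them Fgfr1op2, Anxa4, H2-T10, Cfl1 and Hbb-b2, were called in both comparisons with KHR. The pattern was first drawn as KHR replicate 5 against the other KHR arrays, where 31.9% of the 47 genes on which it stood at least a log2 of 1 apart had the other groups on its side, which did not decide between the explanations, and it was then redefined after those values were seen; chance sets about 1 in 20 groups apart. A mislabelled Notch1-deficient sample is argued against, since Notch1 of KHR replicate 5 was 0.54 above the highest array of the other groups. Less connective tissue on KHR replicates 1 to 4 stays open. A median share of 0.975 of the difference was left after the slope on the Fibroblast and matrix list over the other 19 arrays. That value cannot decide, since the 10 genes were chosen for their gap to those same arrays. The slope was also extrapolated, with a lowest list mean of 6.39 on those arrays and a highest of 6.36 on KHR replicates 1 to 4. A strain or donor variant under some probes remains open, since only Fgfr1op2 of the 10 genes has another probe, and over the 26 genes apart by the looser gap of 0.3 another probe stayed in place for 3 of 6 genes against 20 of 78 among the other genes called in KHR-N-/- against KHR with a log2 difference of at least 0.7 (Fisher exact p = 0.339, 84 genes). A real difference between donors of the KHR tumours was not tested.

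Notch1 in the library labelled KHR-N+/- replicate 3 was at 5.68, the level of the KHR-N-/- arrays. A swap with a KHR-N-/- array is argued against, since the highest KHR-N-/- value lay -0.8 from the lowest of the other 3 KHR-N+/- arrays and so left no partner out of place. An error of the Notch1 probe stays open, since its tests went apart and rest on 1 array. A score over 1580 genes that changed in KR tumours put this array at 0.10, -0.03 from the highest of the other 3 KHR-N+/- arrays (SD 0.15). On that score KHR-N-/- had 0.17 to 0.43, KHR replicate 5 had 0.32 and the other KHR arrays had -0.18 to 0.14. The score cannot decide, since KHR replicate 5, with a high Notch1 signal, lay inside the KHR-N-/- range. On the 50 genes that best part KHR-N-/- from KHR-N+/- without this array it lay at 0.72 of the way to KHR-N-/-. The other 3, each held out in turn, lay at -0.08 to 0.18 (SD 0.14). With 20 to 200 genes these values ran from 0.63 to 0.78 and from -0.16 to 0.33. When 1 of the other 3 was held out, replicate 3 stayed among the KHR-N+/- arrays, so their range has a different reference. A single wrong label or loss of the remaining copy in the tumour (Notch1 difference 0 from the KHR-N-/- mean) cannot be told apart with 1 probe and 1 array.

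Stag3 and Zcwpw1, whose KHR-type and KR-type arrays did not overlap, lie on the same chromosome with 12 measured genes between them. A shift of the whole chromosome neighbourhood is argued against, since the larger median over the neighbouring genes was 0.04, and dimmer KR arrays are argued against, since at least a share of 0.967 of the difference was kept with array intensity as a covariate. A wider rise of germline genes in KHR-type tumours had the values it needs, since 11 other germline genes passed as a list in both comparisons of tumour type (limma fry, the larger adjusted p = 7.35e-05, adjusted over both comparisons). The medians were 0.11 and 0.09 and Spo11 fell by 1.03 between KHR-N-/- and KR-N-/-. The rise was thus carried by few genes, among them Smc1b (0.79 and 0.80) and Piwil2 (0.97 and 0.76). The list also went up in KHR-N+/- against KHR (limma fry, unadjusted p = 0.0127), with 1 of 11 genes passing and a median of 0.08. A rise outside the difference in type is therefore not excluded. It did not pass in KHR-N-/- against KHR, KHR-N-/- against KHR-N+/- or KR-N-/- against KR-N+/- (limma fry, unadjusted p = 0.213, 0.152 and 0.364). The difference in type that the labels name stays open as an explanation.

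Other splits of the same arrays were drawn 100 times per comparison, the real one included. The rule set beforehand argued against chance where under 0.05 of the splits, the real one included, called as many. Of the splits drawn, only the real one reached the count for the 10 genes of KHR-N-/- against KHR-N+/- (highest other 4). The same held for the 1581 genes and 13 lists of KR-N-/- against KR-N+/- (508 and 10) and the 542 genes of KHR-N+/- against KR-N+/- (145). It also held for the 1247 genes and 10 lists of KHR-N-/- against KR-N-/- (534 and 4). The rule was met for the 714 genes and 10 lists of KHR-N-/- against KHR (2 and 3 splits as large), but the highest other gave 1024 and 14. It was met likewise for the 2 lists of KHR-N-/- against KHR-N+/- (4 splits as large, highest other 5). So it was for the 3 lists of KHR-N+/- against KR-N+/- (2 splits as large, highest other 3). In these cases another grouping of the same arrays gave as much, so chance is not excluded. The rule was not corrected for the number of results. It was not met for the 122 genes of KHR-N+/- against KHR (8 splits as large, highest other 699). What lets other splits exceed the real counts was not tested. Where the real count was 0, every split is as large by construction (100 of 100), so the splits decide nothing. This holds for the lists of KHR-N+/- against KHR (0 by fry; highest other 11) and for the interaction, with 0 genes in limma (highest other 496; 793 genes at an unadjusted p under 0.05) and 0 lists (highest other 8).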

How the results depend on the processing

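The intensity covariate, the bead covariate, the block for bead sets and the fit without both doubted arrays (KHR replicate 5 and KHR-N+/- replicate 3) were chosen after seeing the data. For values under the settings below that differ from those in the report, the cause was not tested. Comparisons are named by their groups, N-/- and N+/- standing for genotypes within a type. Over the alternatives other than left-out arrays, 3828 results of named genes other than Notch1 stayed on their side of the threshold with their direction. These include genes that passed neither in the main fit nor in the alternative. Of the rest, 381 lost a call, 79 gained one and 16 changed sign. Calls of lists were kept 491 times, lost 69 times and reversed 4 times. Mean intensity ran from 142.4 to 360.4 on KR arrays and from 204.1 to 366.4 on KHR-type arrays. Signal over background limits the size of at least 21 of 194 named calls, whose dimmer group was detected on no more than 2 arrays. Other calls can be limited too, such as Zcwpw1 in KHR-N-/- against KR-N-/-, which ran from 0.726 to 2.241. The files do not give slides, but bead numbers per probe form 3 sets of 7, 8 and 8 arrays in table order (27 to 30.7, 31 to 38 and 39.2 to 40.4), each holding all 5 groups. A block for these sets, a guess at slides, gave 662, 127, 11, 1575, 589, 1349 and 0 genes and 9, 0, 2, 13, 4, 9 and 0 lists in the order of the report's 6 comparisons between groups and the interaction.

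Median scaling gave 165 genes and 4 lists for KHR-N-/- against KHR, 28 genes for KHR-N+/- against KHR, 0 and 0 for KHR-N-/- against KHR-N+/-, 3 and 0 for KR-N-/- against KR-N+/-, 4543 and 16 for KHR-N+/- against KR-N+/-, and 290 genes for KHR-N-/- against KR-N-/-. It put the median of all genes of the interaction at -0.175. Notch1 became -1.1 for KHR-N+/- against KHR and -1.579 in KR tumours, both losing their calls, -0.005 for KHR-N+/- against KR-N+/-, and 0.188 for KHR-N-/- against KR-N-/-, a changed sign. Signs also changed for Hes1 (0.306) and Nrarp (0.088) in KHR-N+/- against KHR, for Hes1 (0.604), Notch3 (0.83), Plin4 (0.052), Scd1 (0.549) and the Adipocyte list (adjusted p = 0.255) in KHR-N+/- against KR-N+/-, and for Ctsb (0.238), Hes6 (0.182), Hey1 (0.22), Notch3 (0.368) and the Notch receptors list (adjusted p = 0.293) in KHR-N-/- against KR-N-/-.

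Array weights gave 2230, 891, 265, 1080 and 2265 genes for KHR-N-/- and KHR-N+/- against KHR, KHR-N-/- against KHR-N+/-, and the comparisons of type at N+/- and N-/-, with 5 lists for KHR-N+/- against KHR, 8 for KHR-N-/- against KHR-N+/- and 2 for the interaction. Notch1 passed at -1.135 in KHR-N-/- against KHR-N+/-. The muscle covariate gave 153, 55, 5, 12 and 506 genes in that order, with 5, 1 and 1 lists for both comparisons with KHR and for the types at N+/-. There the Skeletal muscle list reversed (adjusted p = 0.00374), but that fit is circular, since the list is its own covariate. Signs changed in the same fit for the Adipocyte list (adjusted p = 0.932), Plin4 (0.236), Pparg (0.237), Scd1 (0.056) and Sprr2d (-0.06), and for Hes1 (0.035) in KHR-N+/- against KHR.

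With only the groups of a comparison in the fit, KHR-N-/- against KHR gave 385 genes and 4 lists, KHR-N+/- against KHR 0 genes, KHR-N-/- against KHR-N+/- 0 and 0, and KHR-N-/- against KR-N-/- 2102 genes, and Notch1 lost its call at -1.466 in KHR-N+/- against KHR. Fewer residual degrees of freedom belong to that setting. Without both doubted arrays, KHR-N-/- against KHR gave 1254 genes, KHR-N-/- against KHR-N+/- 81 genes and 4 lists with Notch1 passing at -1.499, and Hes1 was 0.037 in KHR-N+/- against KHR. The intensity covariate gave 4, 108 and 334 genes for KHR-N-/- against KHR-N+/- and the types at N+/- and N-/-. No detection filter gave 70 genes for KHR-N+/- against KHR. For KHR-N-/- against KHR-N+/- the count was 0 with no background correction and with no filter, 6 with the authors' values, 17 with trend and robust settings and 19 (with 4 lists) with the bead covariate. Camera with an estimated correlation gave 0, 0, 1 and 0 lists for KHR-N-/- against KHR, KR tumours and the types at N+/- and N-/-, and with a preset correlation 4, 12 and 6 for KHR-N+/- against KHR, KHR-N-/- against KHR-N+/- and the interaction. Notch1 in KHR-N+/- against KR-N+/- lost its call at -0.546 with no background correction, -0.719 with an offset of 50, -0.923 with no filter, with trend and robust settings and with only both groups, -0.876 with array weights, -0.963 and -0.664 with the muscle and intensity covariates and -0.55 without both doubted arrays.

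The labels give arrays of the same replicate number no other link, but the number follows table order and so, in part, the bead sets. All arrays numbered 1 lie in the set with 27 to 30.7 beads, and all numbered 5 in that with 39.2 to 40.4. Deviations from the group means correlated on average with r = 0.05 over 43 pairs of the same number (-0.33 to 0.48, 16 over 0.1). Over 168 other pairs the average was -0.013 (-0.54 to 0.57, 28 over 0.1). The main fit did not treat the arrays as paired. The replicate block moved the counts to 788, 136, 7, 1993, 556 and 1544 genes in the order of the report's 6 comparisons between groups (KHR-N-/- and KHR-N+/- against KHR, KHR-N-/- against KHR-N+/-, KR tumours, types at N+/- and N-/-) and to 2 for the interaction, and Notch1 lost its call at -0.902 for the types at N+/-.

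With 1 array left out, the genes called ranged from 461 to 1331 for KHR-N-/- against KHR, 41 to 254 for KHR-N+/- against KHR, 0 to 46 for KHR-N-/- against KHR-N+/-, 897 to 1988 in KR tumours, 307 to 870 and 686 to 1687 for the types at N+/- and N-/-, and 0 to 1 for the interaction (1 without KHR-N-/- replicate 5). The lists ranged from 7 to 14, 0 to 2, 0 to 4, 8 to 13, 2 to 7, 4 to 13 and 0 to 1 in the same order. For lists, 0 without KHR-N+/- replicate 1 or KHR-N-/- replicate 5 and 4 without KHR-N-/- replicate 3 or KHR replicate 5 were found in KHR-N-/- against KHR-N+/-, 1 and 2 without KHR replicates 4 and 5 in KHR-N+/- against KHR, and 8 without KR-N+/- replicate 1 in KR tumours. For the types at N+/- 5, 5 and 7 were found without KHR replicates 3 and 4 and KHR-N+/- replicate 4, at N-/- 5 without KR-N-/- replicate 1 or 2 or KHR-N-/- replicate 3 and 4 without KHR-N-/- replicate 2, and 1 for the interaction without KHR-N+/- replicate 1. Notch1 ranged from -2.71 to -2.49, -1.71 to -1.09, -1.5 to -0.89, -1.87 to -1.56, -1.16 to -0.55, -0.49 to -0.18 and 0.2 to 0.81. It passed at -1.499 without KHR-N+/- replicate 3 in KHR-N-/- against KHR-N+/-, lost its call 14 times for the types at N+/- (-0.993 to -0.55), and Hes1 ranged from -0.389 to 0.018 in KHR-N+/- against KHR (0.018 without KHR replicate 5).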

Other observations

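The genes in this part were chosen after their values were seen. No list of keratins was tested. Of 57 measured keratin and keratin-associated genes, 8 were lower and 1 higher in KHR-N-/- than in KHR tumours, and 48 did not pass. Over all 9732 genes 269 were lower and 445 higher. Beyond those in the report, Krt73 fell by 1.41 (adjusted p = 0.0449), Krt84 by 0.91 (adjusted p = 0.0194) and Krt26, a keratin of the inner root sheath, by 0.69 (adjusted p = 0.0109), and Tchhl1, a relative of trichohyalin, fell by 1.33 (adjusted p = 0.00208). KHR tumours varied widely in Krt34, with an SD of 1.69 (n = 5). In KR-N-/- against KR-N+/- tumours Krt31 fell by 0.87 (adjusted p = 0.0382), Krtap13-1 fell by 1.44 (adjusted p = 0.0473) and Krt26 by 0.52 (adjusted p = 0.0468).

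Of the same 57 genes, 7 were lower and 0 higher in KR-N-/- than in KR-N+/- tumours. Over all 9732 genes 645 were lower and 936 higher, and with median scaling only 3 genes passed in that comparison. Krt13 and Krt4, a pair expressed in the upper layers of the mouth lining, fell by 1.48 (adjusted p = 0.00398) and 2.16 (adjusted p = 0.00966), and Krt23 and Krt79 fell by 1.89 (adjusted p = 0.00116) and 1.49 (adjusted p = 0.0232). Ivl had a mean of 8.19 in KHR, 9.75 in KHR-N+/-, 10.00 in KHR-N-/-, 8.17 in KR-N+/- and 7.39 in KR-N-/-. Ccl11, which attracts eosinophils, fell by 1.47 in KHR-N-/- against KHR (adjusted p = 2.04e-05).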
